A study of Mus musculus with 4 samples.

How the data were processed

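Genomic DNA of bone-marrow-derived macrophages from male C57BL/6 and BALB/c mice was fractionated by methyl-CpG immunoprecipitation, a method that separates DNA fragments by their density of methylated CpG dinucleotides. Per the labels, each preparation gave a pool of weakly methylated (hypomethylated) and a pool of strongly methylated (hypermethylated) fragments. Mice were 8 to 12 weeks old and macrophages were harvested on culture day 7. Each of the 4 two-colour tiling arrays compared the same pool of both strains, with C57BL/6 DNA in the Alexa Fluor 5 channel and BALB/c DNA in the Alexa Fluor 3 channel. No array had the dyes swapped, so a dye effect that is the same on all arrays stays in the pool average described here. A dye effect that differs between the pools and repeats in both replicates would stay in the difference between the pools. Each strain gave 2 independently grown preparations, and the pools of one preparation share a replicate number.

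The deposited values are log10 ratios of the channels for 240662 probes per array, read as such from the values. Per the file headers and labels, neither the log base, the normalization nor the direction of the ratio is stated, and the scanner and extraction software are not given in the sources used here. Base 10 was chosen because runs of probes lie at -0.27 on the deposited scale, averaged over the 4 arrays, and near it in each array. This level is a 1.84-fold ratio in base 10 and 1.20-fold in base 2. If the base were 2, every log2 value given here would be too large by the same factor, and signs, ranks and the limma tests without a size limit would not change. The ratio was read as C57BL/6 over BALB/c, which is likely and not stated; if it ran the other way, the strains would change places in every result. Medians of the deposited columns were 0.00235 and -0.000117 in the hypomethylated pools of replicates 1 and 2, and 0.00763 and -5.48e-05 in the hypermethylated pools. All 4 value columns were mapped to a sample by name.

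Values were converted to log2 and each array was centred on its median. For each replicate, the pool contrast was the log ratio in the hypermethylated pool minus that in the hypomethylated pool, divided by 2. A positive contrast means that the ratio of C57BL/6 to BALB/c DNA was higher in the methylated than in the unmethylated pool. The ratio can still lie on the same side of 0 in both pools. The pool average was the mean log ratio of the pools. A difference in methylation alone would leave it near 0 only if it moved both pools equally and in opposite directions. The noise contrast was the difference between the contrasts of the replicates, divided by 2. Contrasts and averages were tested against 0 with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 on n = 2 replicates, with Benjamini-Hochberg (BH) adjusted p under 0.05. Taking the contrast within a replicate keeps the replicate as a block, since the labels derive same-numbered pools from one DNA preparation. Across probes, the deviations of same-numbered arrays from their pool means correlated at r = -0.00780. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the other steps.

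The tests of probes and their alternatives, the main measure of the ratio's direction and the rule for named probes were fixed before the data were examined. The plan used genomic bins, with single probes as the unit if positions were missing. Probe positions and gene names were not used here and the value table does not pair its probe IDs with genes, so probes were the unit; bins, joined regions in base pairs, location, CpG context and gene lists were not analysed here. The rule names the 2 probe IDs with the largest value in each direction, for the contrast and for the average.

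Further units, all alternatives for them and all alternatives for the ratio's direction were chosen after seeing the data. Contrasts of probes whose ID numbers were 1 apart correlated at r = 0.294 over 167957 pairs, against 0.0115 for 20122 pairs listed next to each other with numbers over 100 apart. The probes were therefore also averaged in 38127 non-overlapping windows of 5 consecutive probes, with a step of at most 5 between probe numbers. The window of 5 was chosen after counts for 3, 5 and 8 probes had been seen. A window was called opposed if both hypermethylated arrays had one sign and both hypomethylated arrays the other. The crossed pattern, in which the sign follows the replicate-by-pool combination, served as its noise counterpart. The windows described singly are the 2 in each direction with the largest contrast among opposed windows with a BH call. Stretches of at least 100 probes with number steps of at most 200 were taken as tiled segments, and groups of at least 5 probes with steps of at most 50 as clusters. Intervals for shares of windows are 95% bootstrap intervals from 1000 resamples. Tiled segments were resampled for windows inside them, and 8294 shorter stretches split by the same number step for windows outside.

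The tests were checked on simulated values with the noise of these data and 200 changed features, 50 at each size. The noise of each feature was drawn independently of its average and of its neighbours. In these data the noise grew with the distance of the average from 0, so the counts need not hold for features with a large average. For the contrast of 240662 single probes, limma recovered 0 of 50 at 0.5, 1, 2 or 4 log2, with 0 false calls. With the noise divided by 50 it recovered 49 of 50 at 0.5 log2 and 50 of 50 at 1. For the average of single probes it also recovered 0 of 50 at each size, with 0 false calls. The 200 simulated changes were few among 240662 probes, which makes the BH threshold strict, so these counts do not carry over to a measure in which many probes differ. For the contrast of 38127 windows, it recovered 13 of 50 at 0.5 log2, 47 at 1, 49 at 2 and 50 at 4, with 9 false calls. For the average of windows it recovered 10, 45, 50 and 50 of 50 at these sizes, with 14 false calls. The number of arrays limits the precision throughout.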

Results

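DNA methylation was compared between macrophages of C57BL/6 and BALB/c, inbred mouse strains, in genomic regions that, by the study's design, hold genes expressed differently between them. The data comprised 4 arrays of 240662 probes each: hypomethylated pools of replicates 1 and 2 and hypermethylated pools of replicates 1 and 2. Deposited log ratios ran from -1.82 to 2.54, with an SD of 0.331 and 0.340 in the hypomethylated and 0.336 and 0.328 in the hypermethylated pools. After conversion to log2, the median absolute deviation was 0.21 and 0.20 in the hypomethylated pools and 0.36 and 0.32 in the hypermethylated pools. All median absolute deviations given here are scaled to equal the SD of normally distributed values. By probe numbers, 101808 probes fell into 182 tiled segments of 105 to 3268 probes and 138854 lay outside them.

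The design sets the pools against each other as mirror images, so that a methylation difference between strains should give log ratios of opposite sign in the 2 pools. Over all probes, however, the arrays of opposite pools correlated positively, with Pearson's r of 0.812, 0.824, 0.859 and 0.872. The hypomethylated arrays correlated at r = 0.919 and the hypermethylated arrays at r = 0.923. These are correlations across probes, which are not independent replicates. Spearman's rho was lower, at 0.668 and 0.696 within pools and 0.389 to 0.440 between pools. The pool average, shared by both pools, had an SD of 1.05 log2 across probes, against 0.27 for the pool contrast and 0.16 for the noise contrast. Averages of replicate 1 correlated with those of replicate 2 at r = 0.958, and contrasts at r = 0.506.

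**Figure D1:**
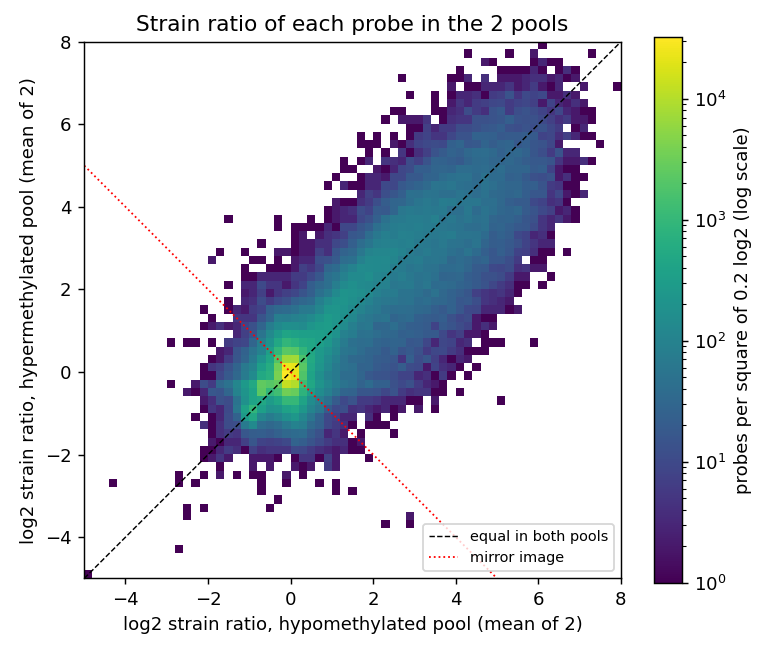
Log2 strain ratio of each probe in the hypomethylated pool (horizontal axis) and the hypermethylated pool (vertical axis), each the mean of 2 arrays, with colour giving probes per square on a log scale. Most of the wide spread follows the dashed line of equal ratios, where 4.72% of probes have an average above 3, and few probes follow the dotted line of opposite ratios.

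Opposite strain ratios in the pools were found in short stretches of neighbouring probes. Of 38127 windows of 5 probes, 151 were opposed with a contrast of at least 0.5 log2 in either direction. In 45 of these the contrast was positive, with relatively more C57BL/6 DNA in the methylated pool, and in 106 it was negative, with relatively more BALB/c DNA there. The noise contrast reached this size in 0 windows, so the crossed pattern could not be counted there. At 0.25 log2 or more, 862 windows were opposed and 28 crossed. The median size of the contrast in the 151 windows was 0.62 log2, or 1.54-fold per pool, and the largest 2.06; in 110 of them both replicates reached 0.5. In 133 of the 151, the pool average lay within 0.5 log2 of 0, as it did in 28540 of all 38127 windows. Opposite signs by themselves keep the average smaller in size than the contrast, so this count is largely set by the definition. Neighbouring windows of one sign formed 139 runs, 43 positive and 96 negative, of which 11 had 2 windows or more and the longest had 3. With the median of the probes in place of their mean, 269 windows were opposed, 133 positive and 136 negative, beside 6 with the crossed pattern, so the excess of negative windows depended on this choice. Leaving out probes called for the pool average gave 74, 31 positive and 43 negative, while windows of 3 probes gave 471 and windows of 8 probes 44.

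The window with the largest negative contrast, which holds probe A_68_P06076154, had a contrast of -2.06 ± 0.40 log2 (SD, n = 2; limma BH adjusted p = 0.0282). Its log ratios were 1.64 and 2.03 in the hypomethylated pools and -1.90 and -2.65 in the hypermethylated pools. A further window, starting at A_68_P24950865, had -1.59 ± 0.05 (SD, n = 2; limma BH adjusted p = 0.0275), from 1.36 and 1.51 in the hypomethylated and -1.74 and -1.74 in the hypermethylated pools. The largest positive contrast, 1.52 ± 0.02 (SD, n = 2; limma BH adjusted p = 0.0275), belonged to the window ending at A_68_P05002005. There the hypomethylated pools were at -0.80 and -0.61 and the hypermethylated pools at 2.27 and 2.41. This window also had a pool average of 0.82 (limma BH adjusted p = 0.000963), while those of the windows with A_68_P06076154 and A_68_P24950865 were -0.22 and -0.15 (limma BH adjusted p = 0.0561 and 0.0716). The next positive window had a contrast of 1.43 ± 0.09 (SD, n = 2; limma BH adjusted p = 0.0275), from -1.95 and -1.78 in the hypomethylated pools to 0.80 and 1.21 in the hypermethylated pools, and a pool average of -0.43 (limma BH adjusted p = 0.0201). All 4 windows were chosen for the size of their contrast, after their values were seen.

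**Figure D2:**
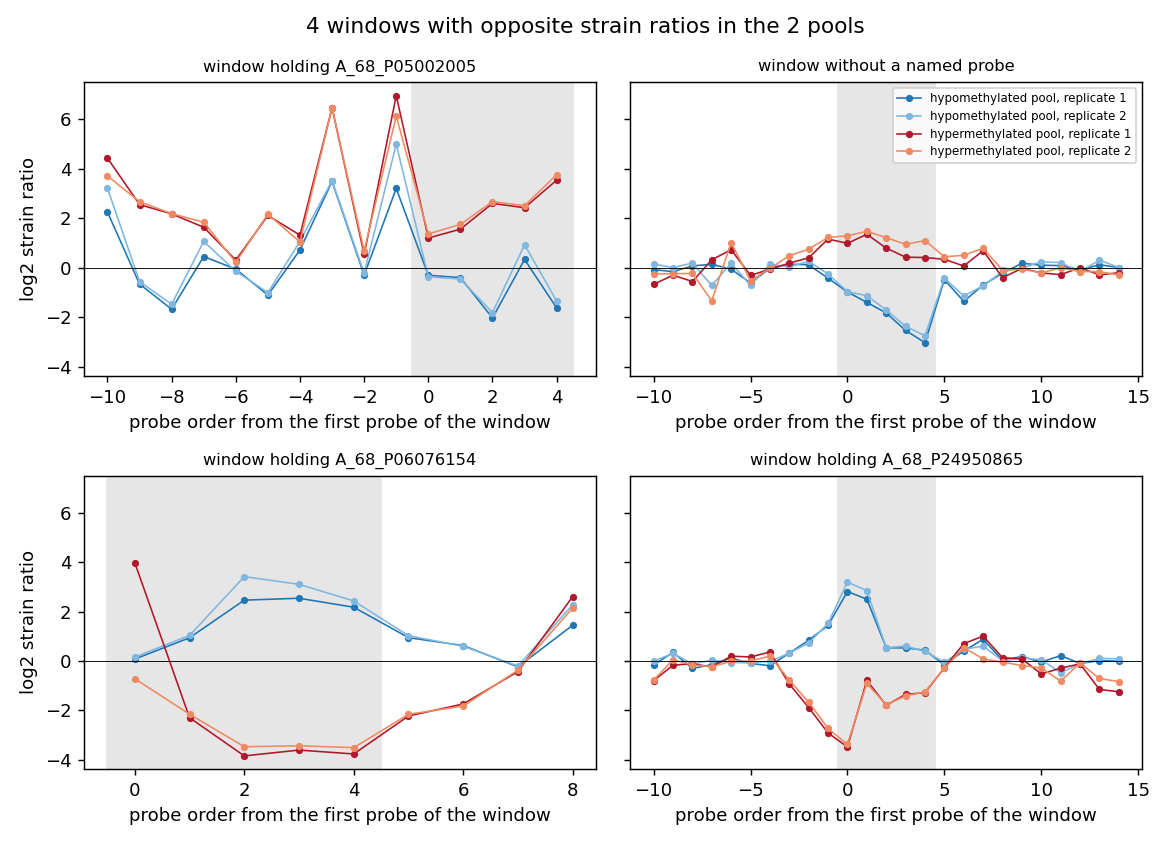
Log2 strain ratio of single probes in each of the 4 arrays (blue, hypomethylated pools; red, hypermethylated pools) along the probe order at the 4 windows with the largest opposed contrasts, with the 5 probes of the window shaded. The replicates of a pool run close together and the pools part over the windows. At the first probe of the window holding A_68_P06076154 the hypermethylated arrays differ from each other, and at the next to last probe of the window ending at A_68_P05002005 all 4 arrays lie above 0.

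The limma test called 1648 of 38127 windows for the contrast, 655 positive and 993 negative. Of these calls, 460 were opposed, 176 positive and 284 negative and the other calls lacked this sign pattern. Of the 151 opposed windows of at least 0.5 log2, 137 had a call, and the highest adjusted p among the 151 was 0.107. These calls changed with the settings. There were 0 at an adjusted p under 0.01, 0 with windows of 3 probes and 0 after leaving out probes with a call for the pool average. Scaling the arrays to the same median absolute deviation gave 5734 calls, 848 positive and 4886 negative. With the median of each window there were 1009, of which 509 were positive and 500 negative. Without the replicate block, limma called 2771 windows on all 4 arrays. In that unblocked fit, leaving out either hypermethylated array gave 0, and leaving out the hypomethylated array of replicate 1 or replicate 2 gave 671 or 1909. Each of these fits leaves a pool with a single array and takes its spread from the other pool, so the counts do not measure how stable the calls are.

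No single probe passed the limma test for the contrast: 0 of 240662 had an adjusted p under 0.05, the lowest being 0.150, while 41825 (17.4%) had an unadjusted p under 0.05. Without the replicate block, limma called 3962 probes, 1868 positive and 2094 negative, and 0 when any single array was left out of that fit. By size, 16831 probes had a contrast of at least 0.5 log2, 7349 positive and 9482 negative, against 4988 for the noise contrast. At 1 log2 or more the counts were 2874 and 148. Among the 193961 probes whose average lay within 0.5 of 0, 281 had a contrast of at least 1, against 59 for the noise contrast. The largest positive contrasts were those of A_68_P05002005, at 2.57 ± 0.02 (SD, n = 2), and A_68_P24427900, at 2.32 ± 0.0037. The largest negative ones were those of A_68_P06076154, at -3.29 ± 0.21, and A_68_P24950865, at -3.21 ± 0.10. Each of the 4 had a limma BH adjusted p of 0.150 and opposite signs in the pools in all 4 arrays.

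Opposed windows were spread over the array. The tiled segments held 80 of the 151, or 0.404% of their 19804 windows (95% interval 0.313 to 0.503). Outside them were 71, or 0.387% of 18323 windows (0.293 to 0.490), a difference of 0.0165 percentage points (-0.126 to 0.154). At least 1 opposed window was found in 50 of the 182 segments, against 56.7 on average when the 80 windows were scattered at random over the tiled windows (43 to 66 in 1000 draws). No segment held more than 5, and 4 segments held windows of both signs.

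Log ratios of the same sign in both pools bear on sequence and copy number differences between the strains, and the series type also names genome variation profiling. The pool average measures this shared part, although a called average does not require the same sign in every array. A methylation difference that moves the pools unequally also shifts the average, so a called average does not exclude it. The limma test on the pool average called 47115 of 240662 probes, 33465 higher in C57BL/6 and 13650 higher in BALB/c. An average above 1 log2 was found for 27010 probes (11.2%) and one below -1 for 1410 (0.586%). Above 3 log2, an 8-fold ratio, were 11352 probes (4.72%), and below -3 were 4. The highest averages were 7.48 ± 0.06 for A_68_P26917882 (SD, n = 2; limma BH adjusted p = 0.00198) and 7.39 ± 0.55 for A_68_P25066114 (limma BH adjusted p = 0.00365). The lowest were -4.84 ± 0.06 for A_68_P05520387 (limma BH adjusted p = 0.00198) and -3.49 ± 0.24 for A_68_P03716924 (limma BH adjusted p = 0.00363). Of the windows, 15081 were called, 12626 higher in C57BL/6 and 2455 higher in BALB/c. At an adjusted p under 0.01, 22333 probes were called, 19855 higher in C57BL/6 and 2478 higher in BALB/c. Without the replicate block, 20170 probes were called as higher in BALB/c, and 7059 when the hypomethylated array of replicate 2 was also left out. With the median of each window, 5872 windows were called.

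Some stretches lay at levels of their own. The largest tiled segment, with 3268 probes, held 1376 probes with a median average of -0.02 log2 up to probe number 31134071. It then stepped to -0.90 for the remaining 1892 probes, a 1.86-fold lower C57BL/6 signal. The medians of the arrays after the step were -0.88 and -0.91 in the hypomethylated pools and -0.84 and -0.89 in the hypermethylated pools. A segment of 253 probes lay at 0.81 (1.76-fold), with a median absolute deviation of 0.28. Segments of 485 and 250 probes had medians of 1.54 and 2.86 but no single level: 54.6% and 71.6% of their probes lay above 1 log2, and the median absolute deviations were 2.38 and 2.14. Between probe numbers 13058615 and 13585326, 149 of 685 clusters of probes had a median average between -1.2 and -0.6 log2, with a mean of -0.88 ± 0.09 (SD over clusters). Elsewhere 12 of 9553 clusters did (0.126%). The bounds of this stretch were set by the clusters themselves, as the part of the probe order where at least 10% of 100 neighbouring clusters lay at this level, so the contrast with the other clusters is partly fixed by that rule. The clusters at this level alternated with others: 487 of the 685 lay within 0.3 log2 of 0, and the level changed 230 times along the probe order. The fold values hold for base 10; in base 2 the step would be 1.21-fold.

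**Figure D3:**
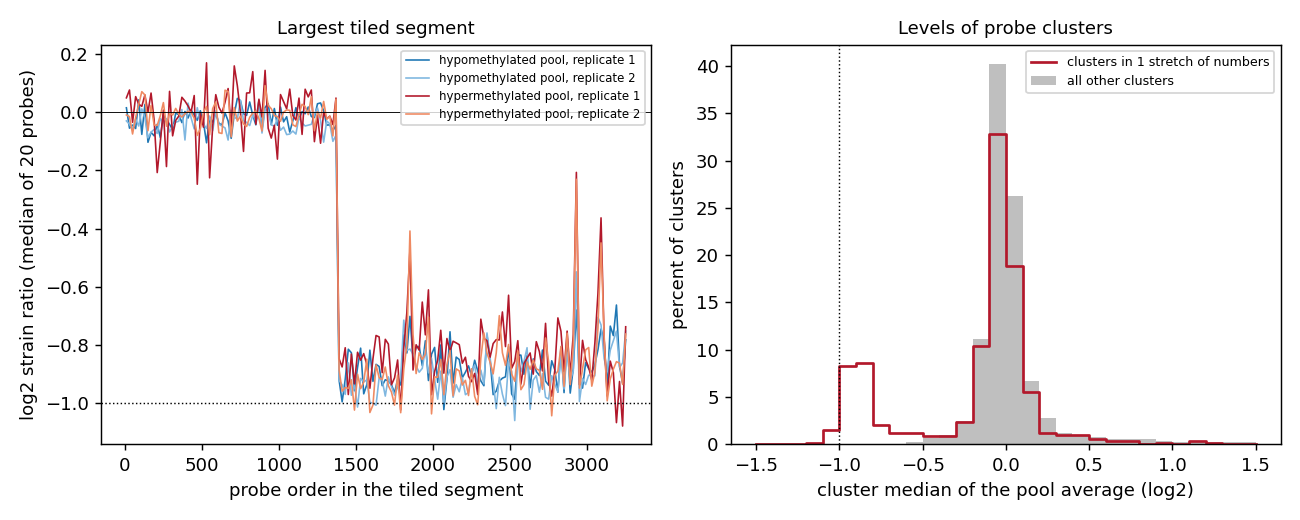
Left, log2 strain ratio (median of 20 probes) in each of the 4 arrays along the probe order of the tiled segment with 3268 probes, stepping from -0.02 to -0.90 in all arrays, with a dotted line at -1. Right, percent of probe clusters at each level of the pool average (log2) between probe numbers 13058615 and 13585326 (red line, 685 clusters) and elsewhere (grey bars, 9553 clusters), where the red line alone has a separate peak near -0.88.

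Windows called for the contrast were often also called for the average. Of the 1648, 1414 (85.8%) had both calls, against 39.6% of all windows with a call for the average. The expected overlap was 652, so the observed count was 2.17 times as high. A two-sided permutation test by circular shifts along the windows gave p = 2.62e-05, the smallest that the 38127 shifts can give. The highest overlap of a shifted set was 1080. Both measures come from the same 4 arrays, so a strain ratio found mainly in a single pool moves both of them. The shifts break this link, so the test cannot tell whether separate strain differences coincide. The spread of the contrast grew with the distance of the average from 0. Its SD was 0.16 log2 for probes with an average within 0.25 of 0, 0.31 for probes with an average below -1, and between 0.51 and 0.60 for probes with an average above 1. The SD of the noise contrast was 0.11, 0.21 and between 0.25 and 0.30 in the same sets.

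**Figure D4:**
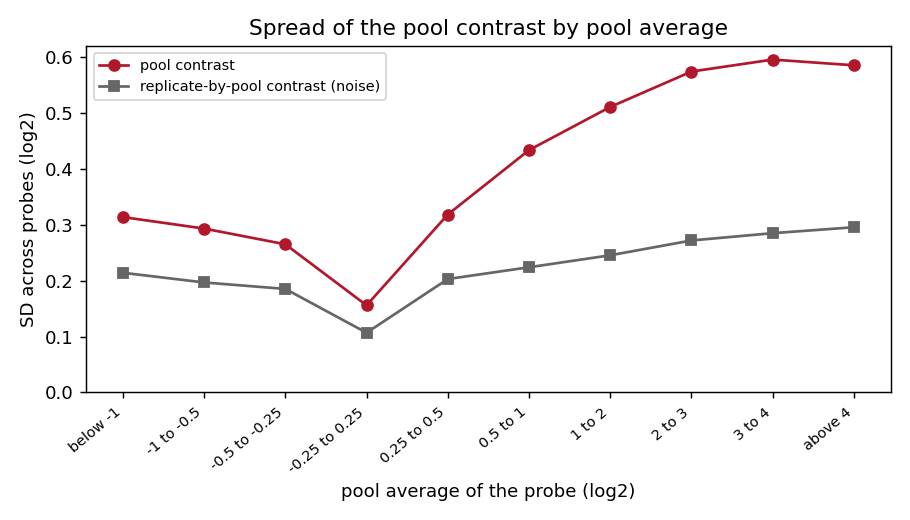
SD across probes (log2) of the pool contrast (red) and of the noise contrast (grey), for probes grouped by their pool average in log2. The contrast spreads from 0.16 near an average of 0 to 0.60 for averages of 3 to 4, and the noise contrast from 0.11 to 0.29.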

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

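The windows and the test of a larger measurement error were chosen after the results were seen, while the rule for the single probes was fixed before the data were examined and the prediction for neighbouring probes was written before its result.

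In 4 windows and 4 single probes the strain ratio moved one way in both arrays of one pool and the opposite way in both arrays of the other. For the windows the difference between the pools was tested, with a limma BH adjusted p of 0.0275 to 0.0282. Their contrasts were 1.52 log2 for the window ending at A_68_P05002005, 1.43 for the next positive window, -2.06 for the window with A_68_P06076154 and -1.59 for the window starting at A_68_P24950865. For the probes the difference did not pass the test (limma BH adjusted p = 0.150). Their contrasts were 2.57 for A_68_P05002005, 2.32 for A_68_P24427900, -3.29 for A_68_P06076154 and -3.21 for A_68_P24950865. The windows were picked as the largest in each direction among the 460 opposed windows with a call. Their opposite signs and an adjusted p under 0.05 were therefore conditions of the choice. The probes were picked as extremes of 240662, and the sizes of both windows and probes are biased upwards. Windows and probes also overlap, since A_68_P05002005, A_68_P06076154 and A_68_P24950865 lie in the windows.

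The pool contrast spread more widely among probes whose pool average lay far from 0. Above an average of 1 log2 its SD was 2.06 times that of the noise contrast, against 1.46 near 0, which argues against measurement error as the whole cause there, although the noise contrast widened too. Below -1 the ratio was 1.47, much as near 0. Contrasts of the replicates correlated at r = 0.371 there, against 0.361 near 0. Larger error that differs between the replicates would, alone, lower both values. They therefore argue against such error as the whole cause below -1 too, although the noise contrast widened there as well. Error shared by both replicates stays open for those probes. Neighbours in the same window with an average near 0 carried 11.2% of the contrast of a probe above 1 (95% interval 10.1 to 12.3, 6117 probes). Beside probes near 0 the share was 43.0% (37.7 to 49.1, 2532 probes). Both intervals resample single probes, although several can lie in the same window and share neighbours, so they are probably too narrow. The 11.2% lay below the limit predicted for a compressed ratio. However, the larger contrast of the probe alone would lower the 43.0% to 18.3%, which is below that limit too. The observed share was lower still, but meeting the limit does not tell the explanations apart. The test therefore leaves open whether background compresses the ratio in the pool that holds little of a locus, or whether methylation differs between the strains at the fragment under a single probe.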

How the results depend on the processing

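All alternatives for windows and for the ratio's direction were chosen after the data were seen, as was the window itself. Of 90 recomputed values, 66 stayed on the same side of the threshold or within the limits of the main value. The 66 include the named probes and windows recomputed from a single replicate, which had been picked for their size. They also include counts of 0 that a stricter setting could only leave at 0. None of the 90 changed sign, but counts cannot do so, and the tally therefore does not measure how stable the results are. For the contrast of single probes, the count of 0 became 3962 without the replicate block 0 again when any single array was left out of that unblocked fit, and was 0 under the other settings run. Probes called for the average fell from 47115 to 22333 at an adjusted p under 0.01; without the replicate block there were 57776, and leaving out single arrays from that unblocked fit gave 37204 to 42423. Windows called for the contrast numbered 1648 in the main setting, 5734 with arrays scaled to the same median absolute deviation, which by construction ties the contrast to the average, 633 at a minimum of 0.5 log2, 0 at an adjusted p under 0.01, 2771 without the replicate block, 0 with windows of 3 probes, 1009 with the median, and 0 without probes called for the average. Leaving out single arrays from the fit without the block, 2771 on all 4 arrays, gave 0 to 1909; there a pool keeps 1 array, assumed to vary like the other pool. Windows called for the average numbered 15081, then 9573 at a minimum of 0.5 log2, 22978 with 3 probes, 9632 with 8 probes, by construction from more and fewer windows, and 5872 with the median. Opposed windows numbered 151, then 471 with 3 probes (8 crossed), 44 with 8 probes, 269 with the median (6 crossed) and 74 without probes called for the average; from a single replicate there were 192 to 260. Mean correlations within pools were 0.921, 0.956 over windows and 0.682 as Spearman's rho; between pools they were 0.842 and, as Spearman's rho, 0.415. Unless a construction is named, the cause was not tested. Leaving out the replicate block moved no other count by over 1.5 times. The overlap at an adjusted p under 0.01 gave no value, as no window was called for the contrast. Bin widths, probes per bin, region gaps, promoter widths and gene list distances were not run, since probe positions were not used here. Signal over background is unknown, so what it limits was not assessed.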

Other observations

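The shares of probes above 1 log2 and the neighbour correlations were looked at after the data were seen, as were the tests of the level near -0.88 log2; the test of the ratio's direction was fixed before, and its alternatives after.

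The tiled segments differed in how many of their probes had a large pool average. The share above 1 log2 ran from 0 to 71.6% per segment, with a median of 7.88% and quartiles of 3.85% and 18.2%. It was under 2% in 31 of the 182 segments and over 20% in 42. The SD across segments was 11.5 percentage points, against at most 2.03 in 100 shuffles of the probes over the segments. The shuffles treat probes as independent, while averages of probes with numbers 1 apart correlated at r = 0.252. The shuffled SD is therefore a low reference. The shares themselves were uneven, with some segments almost free of probes with a large average. Such probes were in the majority only in the segments of 485 and 250 probes, at 54.6% and 71.6%. The next highest share was 40.4%. Called windows for the average formed 8836 runs, and the longest held 52 windows, against 4 for the contrast. Of 38127 windows, 15081 were called for the average and 1648 for the contrast. The larger number of calls alone would lengthen the runs for the average. The segment of 250 probes with a median average of 2.86 log2 had medians of 4.09 and 3.49 in the hypomethylated and 1.79 and 1.63 in the hypermethylated pools.

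Array probes follow the C57BL/6 reference sequence, so variants under them should lower the BALB/c signal in both pools. Probes above 0.5 log2 in the average numbered 34101 and those below -0.5 numbered 12600, a ratio of 2.71. It was 2.86 without centring, 2.28 with arrays scaled to the same median absolute deviation, and 449 with the deposited values read as log2, where 0.5 is a larger deposited value. This is consistent with a ratio taken as C57BL/6 over BALB/c.

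For the 149 clusters near -0.88 log2, an error of single arrays or of 1 pool is argued against: the mean level was -0.86 and -0.89 in the hypomethylated and -0.85 and -0.86 in the hypermethylated pools, and the pools differed by 0.021 log2 (SD 0.19 over clusters). A copy number ratio of 1 to 2 between the C57BL/6 and BALB/c DNA stays open. In the stretch, 149 clusters lay between -1.2 and -0.6 and 20 between -0.6 and -0.3, a ratio of 7.45, against 12 and 180 elsewhere, but the stretch was bounded by these clusters and base 10 was chosen from their level, which in base 2 would lie far from 1 to 2. A ratio of 1 to 2 would also arise if the C57BL/6 DNA held 1 X chromosome and the BALB/c DNA 2, although the labels call all mice male. An inactive X would add clusters more methylated in BALB/c, and 0 of the 149 had a contrast below -0.5. The 149 were picked by their pool average, though, and such methylation could move a cluster's average out of the chosen range. This count therefore cannot decide, and the chromosome of these probes is not known here. An X chromosome difference, other copy number differences and a property of the probes that alternate with those near 0 cannot be told apart.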
